A study of Homo sapiens with 4 samples.

How the data were processed

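The series holds 4 chromatin immunoprecipitation sequencing samples of H1 human embryonic stem cells, an established cell line. Per the labels, the cells were either wild type or treated with a short hairpin RNA against YTHDF1, and were grown in mTeSR1 medium. Each group has 1 library made with an antibody against histone H2A monoubiquitinated at lysine 119 (H2AK119ub) and 1 input library. A peak list was analysed for each of the 2 H2AK119ub libraries. The input libraries were not analysed here. Groups were taken from the sample titles.

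The submitters' processing notes name Trimmomatic 0.35, Bowtie2 2.2.5, SAMtools 1.3.1, Picard, MACS2 2.1.0 and SICER 1.1, with the genome build hg38. They give no role or order for these tools. Which of them called the peaks, and whether the input was used as a control, is not given in the sources used here. The values deposited per peak are a chromosome, a start, an end, a name and a score, with no header. All starts were multiples of 200 bp and all ends lay 1 bp below a multiple of 200 bp, so ends were read as inclusive. Peaks lay at least 0.8 kb apart in both lists.

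The score is the authors' own deposited value per peak, and its unit is not given in the sources used here. It ran from 2.00 upward in both lists. It held no value between 310 and 1000 in the wild-type list and none between 309 and 1000 in the knockdown list. The ceiling of 1000 was reached by 997 wild-type and 643 knockdown peaks. The score was used to rank or filter peaks within their own list and, in 1 test of the closing section that was then set aside, to match genes on their highest score across both lists. The lists hold no read counts, so the sequencing depth of both libraries is unknown and no counting interval could be given. A peak in one list alone can therefore be a region that lay just under the calling threshold in the other library.

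Peaks on chromosomes 1 to 22 and X were used, which left 32791 of 32798 wild-type and 34390 of 34393 knockdown peaks. Covered length is the number of bases inside peaks. Peaks were called shared when they had at least 1 bp in common with a peak of the other list. Overlap by chance was described by 100 random circular shifts of the knockdown list within chromosomes. The extent of each chromosome was taken from its last peak or gene, as no genome sequence was used here.

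Gene positions came from a RefSeq gene table of GRCh38.p14, which shares its coordinates with hg38. The table gives the start and end of each gene but neither strand nor exons. The planned windows around the 5' end were therefore replaced by windows around both annotated ends. A gene was called marked when a peak lay within 2 kb of either end. Its covered length was the number of bases in peaks within 10 kb of either end, with overlapping windows merged. These windows can hold peaks of neighbouring genes. After 153 protein-coding genes with scaffold coordinates were left out, 19821 protein-coding genes remained, among 58413 genes of any kind. Peaks were also assigned by midpoint to the vicinity of a protein-coding gene end (within 2 kb), to the rest of a protein-coding gene, or to sequence outside these genes. The planned split into exons and introns and the comparison with genome-wide shares were not made.

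Each group had 1 H2AK119ub library, so no test was run and no p-value is given. Values of the 2 lists are set side by side. Lists of genes were fixed before the data were examined, as were the windows of 2 and 10 kb, the overlap rule and most alternatives. The 21 lists cover HOX genes, transcription factors of neural, mesoderm and endoderm development, trophoblast and amnion genes, morphogens and growth factors, pluripotency genes, subunits of Polycomb repressive complexes 1 and 2 (PRC1 with the H2A deubiquitinases, and PRC2), m6A writers, erasers and readers, germline genes, cell cycle inhibitors, imprinted genes, neuronal channels and receptors, housekeeping genes, silent tissue-specific genes, metabolic enzymes, zinc finger genes of chromosome 19, clustered protocadherins, olfactory receptors and ribosomal proteins. They hold 1249 distinct genes, of which CDKN1C, JARID2 and MSX2 stand in more than 1 list. For each list, the median per-gene difference in covered length was placed among 10000 random lists of the same size, matched in 10 bins on the mean covered length of both libraries. The percentile describes these 2 libraries only. Because many medians were exactly 0, the mean difference was placed in the same way, a choice made after the data were seen.

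Named genes followed a rule set beforehand. It took the 2 genes with the longest covered length in each list, the list members with the largest decrease and increase of at least 1 kb, YTHDF1, RING1 and RNF2, and the 10 protein-coding genes with the largest decrease and the 10 with the largest increase, without overlapping windows. The rule gave 103 genes, some of which are not reported here. Members of a list marked in 1 library alone, the genes in the widest peaks and the pluripotency factors POU5F1, SOX2 and NANOG were named in addition, after their values were seen.

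Alternatives were the upper 50% of each list by score, lists of equal length, merging of peaks over gaps of up to 3 kb, autosomes only, peaks of at least 2 kb, overlap over 50% of a peak's length, other windows, all annotated genes, at least 500 bp covered, and whole gene spans. The code was tested on simulated data in which the peaks inside or within 2 kb of 200 protein-coding genes were removed from a copy of the wild-type list. Among 19821 genes screened, all 140 of these that had a peak near an end were recovered as marked in the original alone. The covered lengths of 200 windows were checked against a direct count, and 200 were equal. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.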

Results

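H2AK119ub is the histone mark deposited by PRC1, whose catalytic subunits RING1 and RNF2 attach a single ubiquitin to histone H2A. YTHDF1 is a cytoplasmic protein that binds m6A, the methylated adenosine of messenger RNA. The series set the H2AK119ub profile of YTHDF1 knockdown H1 embryonic stem cells beside that of wild-type H1 cells. Each group had 1 H2AK119ub library and therefore no replicate, so no difference below could be set against a replicate spread and none was tested. The depth behind the peak lists is unknown. Positions are in hg38.

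The first comparison asked how much of the genome the mark occupied. The knockdown list held slightly more peaks than the wild-type list, but they were narrower and covered less DNA. It had 34390 peaks against 32791, a difference of 4.88%. They covered 168 Mb in the knockdown and 195 Mb in the wild type, a difference of -13.7%. The HOXA, HOXC and HOXD clusters, which encode transcription factors of the body axis, lay in domains of nearly equal width in both lists, while peaks of 20 kb or more were fewer in the knockdown.

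The median peak width was 3.6 kb in the knockdown and 4.4 kb in the wild type, and the mean widths were 4.89 and 5.95 kb. Peaks of 20 kb or more numbered 603 in the knockdown and 927 in the wild type. Those of 50 kb or more numbered 39 and 86. The widest wild-type peak spanned 198 kb over MACROD1, FLRT1, OTUB1 and COX8A on chromosome 11 (63964201 to 64161800), where 6 knockdown peaks, the widest of 157 kb, covered 95.4% of it. The HOXA cluster on chromosome 7 lay in a single peak in both lists, of 173 kb in the wild type (27086001 to 27259200) and 172 kb in the knockdown (27085801 to 27257600). The HOXC cluster lay in peaks of 143.8 and 143.6 kb, and the HOXD cluster in peaks of 130.4 and 130.2 kb. The HOXB domain measured 137 kb in the wild type, and 3 knockdown peaks, the widest of 115 kb, covered 97.52% of it. A wild-type domain of 149 kb over the imprinted genes KCNQ1, CDKN1C and PHLDA2 on chromosome 11 met 7 separate knockdown peaks, which covered 93.9% of it. With peaks under 2 kb left out, the difference in peak number was -0.311%, so the higher number rested on narrow peaks. Its covered length stayed lower under each alternative tried.

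The covered length was lower in the knockdown list on each of the 23 chromosomes. The ratio of knockdown to wild type was lowest on chromosome 22 (0.730), followed by X (0.772), 21 (0.796) and 19 (0.803), and highest on chromosome 18 (0.950). Chromosomes 21, 22 and X also had fewer peaks in the knockdown list, with 1181 against 1267 on chromosome 22, while the other 20 chromosomes had more. Without chromosomes 19, 21, 22 and X, a choice made after the data were seen, the difference in covered length was -12.3%.

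**Figure D1:**
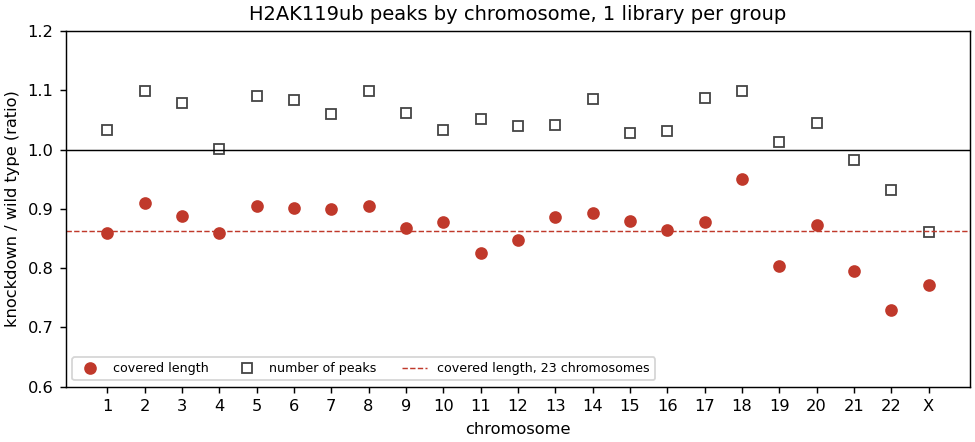
Ratio of knockdown to wild type (y axis) for each chromosome (x axis), with filled circles for the length covered by H2AK119ub peaks and open squares for the number of peaks, from 1 library per group. The dashed line is the covered length ratio over the 23 chromosomes, and the circles lie between 0.730 on chromosome 22 and 0.950 on chromosome 18, all under 1.

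The second comparison asked whether the mark lay in the same places. Most peaks of each list touched a peak of the other. Of the wild-type peaks, 23427 (71.4%) shared at least 1 bp with a knockdown peak, and 25494 knockdown peaks (74.1%) shared at least 1 bp with a wild-type peak. Single peaks held the HOXA and HOXD clusters in both lists, and the knockdown peaks there lay 99.9% and 100% inside wild-type peaks. The unshared peaks were the narrower and lower-scored ones of each list.

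The lists had 119.4 Mb in common, which gave a Jaccard index of 0.489. After circular shifts of the knockdown list the index had a median of 0.0449 and a maximum of 0.0594, and the share of knockdown peaks touching a wild-type peak had a median of 13.8% and a maximum of 17.1%. Unshared peaks numbered 9364 in the wild type and 8896 in the knockdown, covering 34.2 and 26.7 Mb. In the wild-type list the median width was 5 kb for shared and 3.4 kb for unshared peaks, with median scores of 24.2 and 8.52. In the knockdown list the widths were 4.2 and 2.8 kb and the scores 19.96 and 7.90. Among 16990 pairs of peaks that touched only each other, the knockdown peak was narrower in 59.8%, wider in 35.7% and equal in 4.46%, and the median ratio of widths was 0.889. A wild-type peak touched several knockdown peaks in 3469 cases, and a knockdown peak several wild-type peaks in 2169 cases. When at least 50% of both peaks had to overlap, 47.5% of wild-type and 45.3% of knockdown peaks were shared.

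The third comparison asked which genes carried the mark near their ends. The number of marked protein-coding genes was equal in both lists, 13761 of 19821 (69.4%), although the genes were not all the same. Both lists marked 12813 genes, the wild-type list alone marked 948 and the knockdown list alone 948. No other setting gave equal numbers. With lists of equal length, 1051 genes were marked in the wild type alone and 881 in the knockdown alone, and within 5 kb 853 and 920. All 39 HOX genes and all 45 neural transcription factor genes were marked in both lists. Of the 20 genes of the m6A machinery, 15 were marked in the wild type and 12 in the knockdown.

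The m6A genes marked in the wild type alone were METTL3, which encodes the catalytic methyltransferase subunit, CBLL1, YTHDC1 and YTHDC2, and METTL16 was marked in the knockdown alone. METTL3 had 5.14 kb in peaks in the wild type and none in the knockdown. Among the pluripotency genes, 24 of 28 were marked in each list. DPPA4 and GDF3 were marked in the wild type alone and NANOG and TERF1 in the knockdown alone. Of the endoderm factors, 16 of 18 were marked in the wild type and 18 in the knockdown. HNF4A, which regulates liver genes, was marked in the knockdown alone. WNT16, RBBP7, RB1, NDN, SYN2, APOA2 and MYH7 were marked in the wild type alone, as were the germline genes SYCP1 and TEX101. PHC3, MTF2, SOHLH2 and the housekeeping genes DDX5, PSMB4 and TBP were marked in the knockdown alone, as were the enzyme genes HMGCS1, NDUFS1 and PFKM. The 240 zinc finger genes of chromosome 19 had 138 marked members in the wild type and 143 in the knockdown, with 21 marked in the wild type alone and 26 in the knockdown alone. Of the 81 ribosomal protein genes, 58 and 62 were marked, of the 53 clustered protocadherins 32 and 34, and of the 387 olfactory receptor genes, which are silent outside olfactory neurons, 12 and 14. The protocadherins PCDHGB2, PCDHGB5, PCDHGB7 and PCDHGA11 share an annotated end (141512975). In each list the same peak there marked all of them, so the protocadherin counts do not stand for separate peaks. Since strand was not used here, a marked end can be either end of the gene. A gene marked in both lists can also be marked at opposite ends, as SDHB was.

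The fourth comparison asked how far the mark extended around fixed groups of genes. In percent of the wild-type mean, the neural, mesoderm and endoderm transcription factor genes differed less between the lists than all protein-coding genes did. This held for other lists too, among them the metabolic enzyme (-1.91%), pluripotency (-3.65%) and cell cycle inhibitor genes (-5.04%). The m6A, silent tissue-specific, chromosome 19 zinc finger, PRC2, housekeeping, germline and imprinted genes differed more, but in the upper 50% of peaks by score the m6A, housekeeping and imprinted genes did not. The mean covered length of the HOX genes was 26.1 kb in both lists, a difference of -0.0393%. It was 5.88 kb in the wild type and 4.01 kb in the knockdown for the m6A genes (-31.9%), and 8.79 and 7.70 kb for all protein-coding genes (-12.4%).

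Of the 39 HOX genes, 35 had equal covered lengths in the lists, and 34 had windows filled to their ends in both, so these could show neither an extension nor a narrowing farther out. HOXA3 and HOXB3 had 40.0 kb in each list. For the 45 neural factors, 11 had longer and 25 shorter covered lengths in the knockdown, with means of 22.5 against 23.2 kb (-2.65%) and a median difference at percentile 99.8 of the matched random lists. EMX1, a forebrain homeobox gene, had 38.5 against 38.7 kb, and LHX2, another, 38.3 against 40.0 kb. Wild-type peaks filled both windows. The whole peaks at the gene ends summed to 40 against 73.2 kb for EMX1 and 47.8 against 55.2 kb for LHX2. NEUROD1, a factor of neuronal differentiation, had 16.1 against 24.3 kb, and PAX8, a factor of thyroid and kidney, 17.2 against 12.4 kb. The PAX8 difference was 1.80 kb within 5 kb, and the peaks within 2 kb of its ends measured 10.2 against 12.4 kb. The 32 mesoderm factors had means of 19.8 against 20.4 kb (-2.92%), with 12 longer and 14 shorter and a median difference at percentile 99.7. Their mean difference was -0.596 kb. In the upper 50% by score it was -1.25 kb (-6.26%), where that of all protein-coding genes was -0.932 kb (-13.3%). Over whole gene spans it was -2.77 percentage points (-3.42% of the wild-type mean), against -2.94 (-11.2%) for all protein-coding genes. Among them, TBX3 had 33.0 against 33.9 kb and OSR1 22.4 against 19.6 kb (a difference of 0.4 kb within 5 kb of its ends). TBX1, which acts in the pharyngeal arches and lies on chromosome 22, had 30.6 against 36.6 kb, and MEOX1, a somite factor, 16.3 against 24.6 kb (-2 kb within 5 kb). The 18 endoderm factors had means of 19.77 against 19.95 kb (-0.928%), with 4 longer and 13 shorter and a median difference at percentile 87.1. Their mean difference became positive with the upper 50% of peaks by score (0.0483 kb). CDX2, an intestinal factor, had 28.1 against 28.4 kb, and PDX1, a pancreatic factor, 21 against 24.2 kb. Within 5 kb the difference was 0 kb for CDX2, PDX1, EMX1 and TBX3, but peaks filled these windows in both lists, so no difference could show. The whole peaks measured 36.4 against 34.8 kb at CDX2, 21 against 26.4 kb at PDX1 and 46.2 against 48.6 kb at TBX3.

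**Figure D2:**
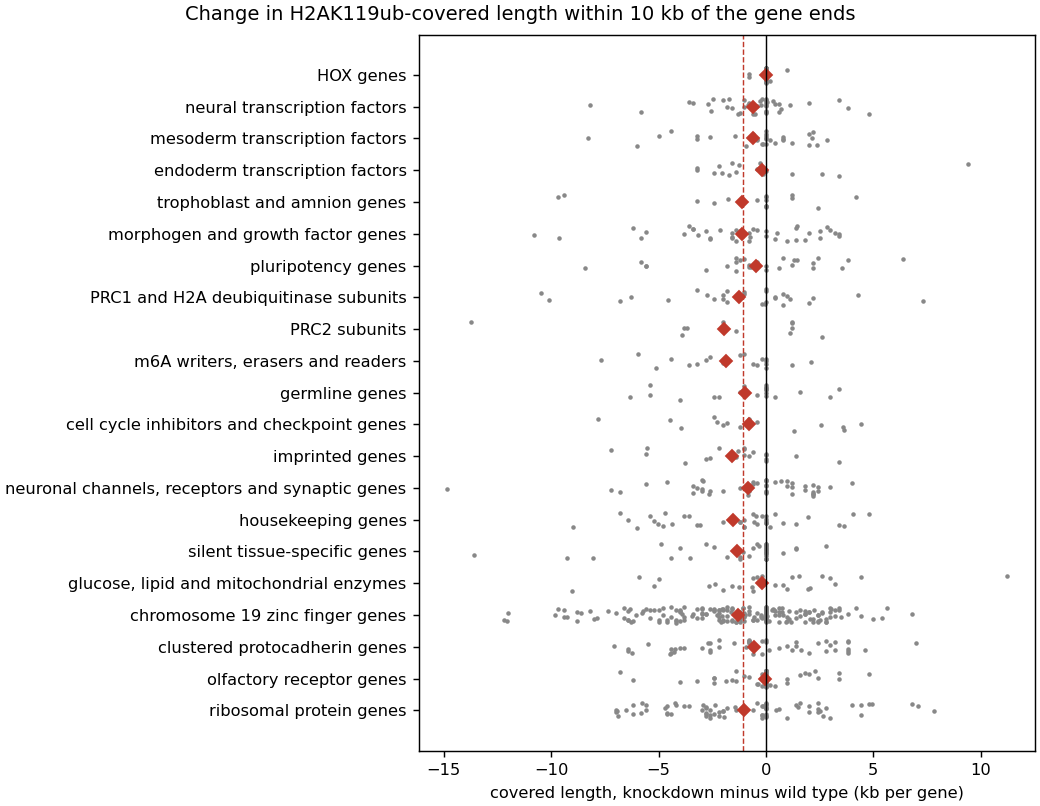
Difference in covered length within 10 kb of the gene ends, knockdown minus wild type (x axis, kb per gene), for the genes of each fixed list (y axis). Each gray point is a gene, red diamonds are list means, and the dashed red line is the mean of all protein-coding genes (-1.09 kb). Most HOX windows were filled by peaks in both lists, which puts their points at 0, and the mean of the m6A genes is -1.87 kb.

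The 28 pluripotency genes had means of 12.5 kb in the knockdown and 13.0 kb in the wild type (-3.65%), with 11 longer and 15 shorter. In the upper 50% by score the difference was -12.6%, against -13.3% for all protein-coding genes. POU5F1, which encodes the pluripotency factor OCT4, had 18.0 against 16.7 kb, and SOX2 had 16.9 against 18.7 kb. NANOG had 2.2 kb against none. LEFTY2, which encodes an inhibitor of NODAL, had 18.6 against 12.2 kb, and PODXL, which encodes a surface glycoprotein of stem cells, 11.6 against 20 kb. OTX2 and ZIC2 had 29.3 against 30.1 kb and 24.98 kb in both. Peaks filled the ZIC2 window in both lists, and the whole peak there measured 37.4 against 40.4 kb. The 16 trophoblast and amnion genes had means of 15.6 against 16.7 kb (-6.67%). The difference was -3.47% without KRT7, -2.60% within 5 kb and -8.63% in the upper 50% by score. TFAP2A had 40.0 kb in both lists, GATA3 29.8 against 25.6 kb, and the keratin gene KRT7 22.5 against 32.2 kb (-1.6 kb within 5 kb). Of the 42 morphogen and growth factor genes, 15 had longer and 25 shorter covered lengths, with means of 16.1 against 17.2 kb (-6.48%). WNT10A had 39.3 kb in both lists, and WNT7B on chromosome 22 had 18.8 against 29.6 kb.

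Of the 29 PRC1 and deubiquitinase genes, 26 were marked in the wild type and 27 in the knockdown, and of the 12 PRC2 genes 9 in each. The PRC1 and deubiquitinase genes had means of 14.9 kb in the knockdown and 16.1 kb in the wild type (-7.73%), with 10 longer and 16 shorter. RING1 had 22.8 against 21.7 kb and RNF2 4 against 5 kb. PHC2, a polyhomeotic subunit, had 4.20 against 14.7 kb, and ASXL1, a partner of the deubiquitinase BAP1, 31.1 against 37.4 kb, with -0.719 kb within 5 kb. The whole peaks near the ends of ASXL1 summed to 31.4 against 95.8 kb. The widest wild-type peak among them, of 58.2 kb, lay outside the gene body (32441201 to 32499400). CBX7, a chromodomain subunit, had 33.1 against 25.8 kb, but its difference was -0.720 kb within 5 kb of its ends. The PRC2 genes had means of 7.23 against 9.17 kb (-21.1%). The difference was -10.1% without PHF19, and with all 12 genes -8.71% within 5 kb, against -10.9% for all protein-coding genes. PHF19, an accessory subunit, was marked in neither list, so the peaks in its window lay more than 2 kb from its ends. It had 2.07 against 15.8 kb, with -3.32 kb within 5 kb. EPOP had 20.9 against 19.8 kb. Within 5 kb neither RING1 nor EPOP could differ, since peaks filled those windows in both lists. The whole peaks measured 29.6 against 20 kb at RING1 and 21.6 against 19 kb at EPOP. In the m6A list, 2 genes had longer and 14 shorter covered lengths, and the median difference lay at percentile 6.25 and the mean difference at 3.51. In the upper 50% by score the mean was 3.67 against 3.90 kb (-5.90%), at percentile 72.7, against -13.3% for all protein-coding genes, and the ratio of whole peak widths lay at percentile 30.6. YTHDF1 itself (chromosome 20, 63195429 to 63216131) had 17.1 against 24.8 kb. A peak there shows neither the presence nor the loss of YTHDF1 RNA, so the knockdown was not checked. IGF2BP2, an RNA-binding reader, had 11.4 against 10.2 kb.

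The 40 housekeeping genes had means of 7.10 kb in the knockdown and 8.65 kb in the wild type (-17.9%), with 9 longer and 26 shorter. Their median difference lay at percentile 18.5 and their mean difference at 23.7, and in the upper 50% by score the means differed by -10.1%. The whole width of their peaks, where both lists marked the gene, had a median ratio of 0.695, at percentile 2.67 of lists matched on width. ENO1, the glycolytic enolase, had 4.80 against 13.8 kb, and the elongation factor gene EEF2 16.4 against 23.2 kb. The RNA helicase gene DDX5 had 4.80 kb against none. The 81 ribosomal protein genes had means of 8.57 against 9.62 kb (-10.9%), with 23 longer and 47 shorter and a median ratio of whole peak widths of 0.728 (percentile 2.93). Their median difference in covered length lay at percentile 38.6 and their mean difference at 67.5. RPL4 had 7.80 kb against none. The 26 metabolic enzyme genes had means of 8.36 against 8.52 kb (-1.91%), but the difference was -11.3% in the upper 50% by score. Among them, SDHB, a subunit of succinate dehydrogenase, had 20.1 against 8.91 kb, the largest increase in the list (11.2 kb). The list mean without SDHB was not computed. The SDHB difference was 5.12 kb within 5 kb. The peaks within 2 kb of its ends lay at opposite ends of the gene. They measured 2.8 kb in the knockdown (17052801 to 17055600) and 2.4 kb in the wild type (17014601 to 17017000). The 240 chromosome 19 zinc finger genes had means of 4.62 against 5.92 kb (-22.0%), with 60 longer and 117 shorter. Their median difference was 0 kb, at percentile 50.7, and their mean difference of -1.30 kb lay at percentile 0.07 of matched lists from all chromosomes but at 23.4 of matched lists from chromosome 19. The other 1170 protein-coding genes of chromosome 19 had -1.12 kb when weighted to the same covered lengths. The whole width of the peaks had a median ratio of 0.720 at the 117 zinc finger genes marked in both lists and 0.789 at the other genes of the chromosome, at percentile 7.04 of width-matched lists from it. In the upper 50% by score the means differed by -24.9%, at percentiles 0.41 and 27.6. ZNF526 had 10.2 against 22.4 kb and ZNF628 27.9 kb in both lists. Peaks filled the ZNF628 window in both lists, and the whole peak there measured 37.4 against 58 kb.

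The 41 silent tissue-specific genes had means of 4.61 kb in the knockdown and 5.95 kb in the wild type (-22.6%), with the median difference at percentile 50 and the mean difference at 3.93, but at 46.8 in the upper 50% by score. MYH6, a cardiac myosin gene, had 8.81 against 22.4 kb. The 48 neuronal channel, receptor and synaptic genes had means of 8.87 against 9.71 kb (-8.67%). GRIN1, a glutamate receptor gene, had 38.2 kb in both lists, and the synaptotagmin gene SYT6 had 10.5 against 25.3 kb. The 20 imprinted genes had means of 9.50 against 11.1 kb (-14.4%), with 2 longer and 14 shorter, and KCNQ1 had 27.2 against 32.8 kb. The 20 germline genes had means of 4.83 against 5.82 kb (-17.1%), and TDRKH had 3.4 against 9.73 kb. The 15 cell cycle inhibitor genes had means of 14.6 against 15.3 kb (-5.04%), with CDKN2A at 37.8 against 34.2 kb (0.849 kb within 5 kb) and CDKN2C at 15.6 against 23.4 kb. The mean difference of this list was -1.72% in the upper 50% by score, -1.82% without CDKN2C and -10.1% within 5 kb. The 53 clustered protocadherins had means of 8.99 against 9.54 kb (-5.86%), but their mean difference was 0.369 kb within 5 kb of the ends and -1.47 kb (-17.8%) in the upper 50% by score. Members that share an annotated end repeat the coverage there in these means. The olfactory receptor genes had means of 0.277 against 0.310 kb (-10.5%), and this difference too was positive within 5 kb (0.00224 kb). With windows of 10 kb, the mean difference was below 0 in all 21 lists and the median difference in 13. The median difference was below 0 in 6 lists within 5 kb of the ends and in 8 over whole gene spans.

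Across all protein-coding genes, the largest differences were shorter coverage in the knockdown at PRAME, SPDEF and FBXO46 and longer coverage at ALG9, KIF3B and APBB1. PRAME, a cancer-testis antigen gene on chromosome 22 (22547701 to 22559265), had 29.6 kb in peaks in the wild type and 4.20 kb in the knockdown. SPDEF, which encodes an ETS factor of goblet cells, had 35.7 and 10.6 kb (chromosome 6, 34537802 to 34556329). FBXO46 on chromosome 19 had 32.0 and 8 kb, and the readthrough gene TPTEP2-CSNK1E on chromosome 22 had 28.6 and 5.20 kb. The airway mucin gene MUC5B had 27.2 and 5.80 kb, TNFRSF8 25.4 and 4.10 kb, RAPGEF1 23.2 and 2.60 kb, NCLN 31.3 and 12 kb, and LPCAT1 31.1 and 11.8 kb. SOX10, a neural crest factor gene on chromosome 22, had 27.0 and 8 kb. In the other direction, ALG9, a mannosyltransferase gene on chromosome 11 (111768025 to 111871581), had no coverage in the wild type and 15.8 kb in the knockdown. The kinesin gene KIF3B had 7.61 and 23 kb, APBB1 8.40 and 23.3 kb, and CSF3R, the receptor gene for granulocyte colony-stimulating factor, 6.60 and 18.8 kb. RDH11 and EFHD1 had none in the wild type and 12.4 and 11.8 kb in the knockdown. DBH, which encodes the enzyme that makes noradrenaline, had 9.20 and 21 kb, MAVS, an antiviral adaptor gene, 3.60 and 15.4 kb, and PADI4 6.40 and 17.8 kb. These genes were picked as the extremes of 19821, so their differences include the chance part of each.

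**Figure D3:**
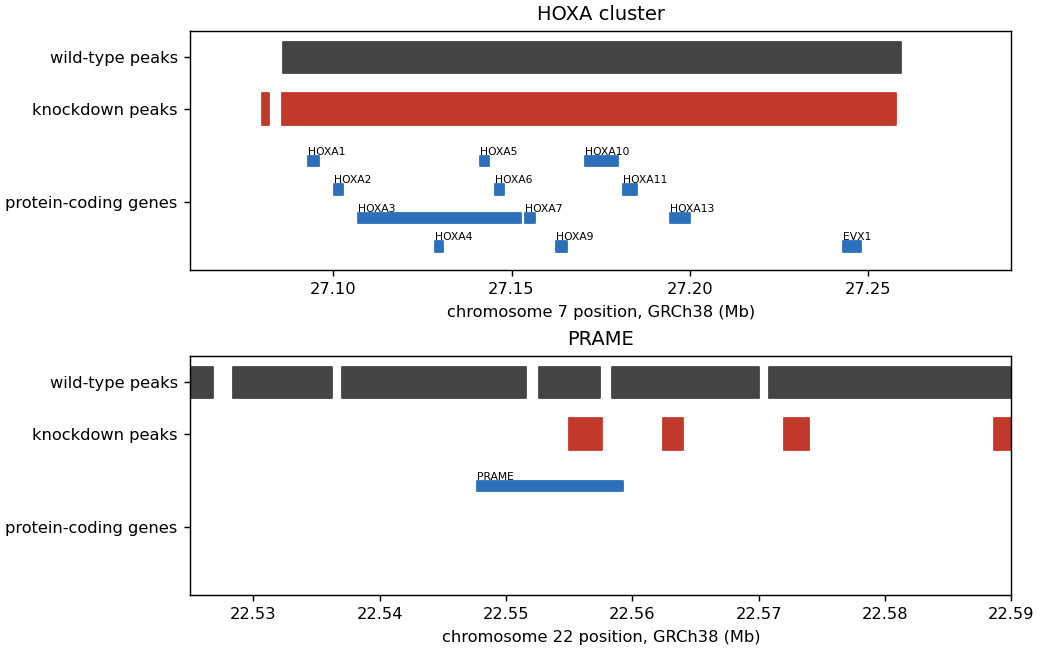
H2AK119ub peaks of the wild type (gray) and the knockdown (red) and protein-coding genes (blue) along chromosome 7 at the HOXA cluster and along chromosome 22 at PRAME (x axis, position in Mb), with readthrough genes not drawn. The HOXA peak spans 173 kb in the wild type and 172 kb in the knockdown, and around PRAME 29.6 kb lie in peaks in the wild type and 4.20 kb in the knockdown.

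The fifth comparison asked where peaks lay relative to protein-coding genes. Their distribution was similar in the lists. Peaks with a midpoint within 2 kb of a gene end made up 31.4% of the wild-type list and 31.8% of the knockdown list. Peaks elsewhere in a protein-coding gene made up 36.9% and 35.6%, and peaks outside these genes 31.7% and 32.6%. When each base was assigned, the vicinity of gene ends held 27.0% of the wild-type and 28.9% of the knockdown coverage, and the rest of the genes 40.5% and 38.0%.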

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

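The covered length with lists of equal length and the runs without chromosomes 19, 21, 22 and X, on genes of at most 5 kb, with the mean difference per list, with whole peak widths, without the member of largest decrease and with random lists from chromosome 19 were chosen after the data were seen, and the others beforehand. The lower covered length of the knockdown list held under all 6 alternatives, from -12.3% to -16.3%. The difference in peak number was 7.33% after merging over 3 kb gaps and -0.311% for peaks of at least 2 kb, the latter because the knockdown list holds more narrow peaks. Shared peaks, in percent of the wild-type and knockdown lists, were 58.6 and 66.9 with 50% of a peak's own length covered, 47.5 and 45.3 with reciprocal overlap, 75.7 and 78.1 in the upper 50% by score, 70.2 and 76.0 with lists of equal length, and 73.0 and 73.1 after merging. Marked protein-coding genes in the wild type and knockdown numbered 13533 and 13505 within 1 kb and 14268 and 14335 within 5 kb. With lists of equal length they numbered 13761 and 13591. Among all annotated genes, 23207 and 22972 were marked, 2624 in the wild type alone and 2389 in the knockdown alone. Among genes of at most 5 kb these counts were 1790, 1769, 109 and 88. Both settings differ in the genes counted. Lists with a median difference below 0 numbered 6 within 5 kb, 8 over gene spans and 21 by whole peak width. Lists with a mean difference below 0 numbered 18 within 5 kb, 18 over gene spans, 20 in the upper 50% by score, 21 with lists of equal length and 19 without the member of largest decrease. Leaving out the largest decrease can only raise a list's mean, and the member of largest increase was not left out in turn. The mean difference of the chromosome 19 zinc finger genes lay at percentile 0.07 of random lists from all chromosomes and 23.4 of those from chromosome 19. Peaks near a gene end made up 27.0% and 28.9% by base, since wide peaks then count by length.

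The sign of the mean difference turned positive for the endoderm factors in the upper 50% by score (0.0483 kb) and over gene spans (0.5001 percentage points), for the neural factors over gene spans (0.0289 percentage points), and within 5 kb for the protocadherins (0.369 kb) and olfactory receptors (0.00224 kb). Within 5 kb, single genes turned as well, to -0.720 kb for CBX7, -2.66 kb for FASN, 0.600 kb for HSP90AB1, 1 kb for IGF2, -0.800 kb for OR1F1, 1.40 kb for PCDHGB7 and 0.948 kb for TPI1. The cause of these turns was not tested. Within 5 kb, 32 of the 103 named genes lay within a factor of 1.5 of the main difference and 64 beyond it with no turn. Of the 21 lists, 7 lay within that factor and 12 beyond it within 5 kb, 10 and 10 in the upper 50% by score, and 21 and 0 with lists of equal length. Gene spans are in another unit and were left out of these counts. Windows of 5 kb are shorter than those of 10 kb, so differences in kb tend to be smaller within 5 kb. For all protein-coding genes the mean difference was -0.638 kb (-10.9%) within 5 kb and -1.09 kb (-12.4%) within 10 kb. The counts beyond the factor within 5 kb therefore do not by themselves show unstable differences. The planned windows at the 5' end alone, the split into exons and introns, and the genome-wide shares were not run, since strand, exons and sequence were not used here. No paired analysis was possible because each group had 1 H2AK119ub library and no test was made. The unknown depth limits every count of peaks in 1 list alone.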

Other observations

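The correlation with gene density was chosen after the ratios per chromosome had been seen, and the regions in the next paragraph were picked after their values were seen. The patterns weighed here were noticed in the same data, and the other tests on them had bounds set before their values were computed.

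The immunoglobulin lambda locus on chromosome 22 (22026076 to 22922913), which is rearranged and used only in the B cell lineage, held H2AK119ub peaks in both lists. They covered 651 kb of it (72.6%) in the wild type and 377 kb (42.0%) in the knockdown, a ratio of 0.579 against 0.743 for the rest of chromosome 22. PRAME, the protein-coding gene with the largest decrease in coverage, lies inside this locus. The heavy chain locus on chromosome 14 and the kappa locus on chromosome 2 held no peak in either list. Of the T cell receptor loci, the beta locus held 15.9 kb in the wild type and 13.8 kb in the knockdown, the alpha locus 0 and 4.80 kb, and the gamma locus 0 and 3.86 kb.

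Several wide domains of the wild type met separate knockdown peaks. A wild-type domain of 129 kb over TCF20 and NFAM1 on chromosome 22 met 8 knockdown peaks covering 89.0% of it, and a domain of 138 kb on chromosome 16 over STUB1, RHOT2 and neighbouring genes met 2, the wider of 97.8 kb. The knockdown list held a domain of 75.4 kb over the neural genes ZIC1 and ZIC4 that lay 98.9% inside a single wild-type peak.

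The knockdown list had narrower peaks and less covered length. The tables argue against the splitting of wide peaks at short gaps as the whole cause, since the difference in covered length was still -12.95% after merging over gaps of up to 3 kb. A shallower or weaker knockdown library stays open. Of the upper 50% of knockdown peaks by score, 7.18% lay where the wild-type list had no peak, more than the 5% set beforehand as too many for a thinned copy of 1 profile. That bound was judged wrong for this design after the value was seen, since 1 library per group leaves unknown how many such peaks repeat libraries have, and the wild-type list had a similar share (8.33%). Less H2AK119ub in the knockdown stays open as well, untested, and cannot be told apart from that difference in the libraries.

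The shortfall was uneven by chromosome. A difference in copy number of chromosome 22 between the cultures could not be excluded, since the ratios over 3 equal parts of it were 0.661, 0.735 and 0.780, and their range of 0.119 lay between the bounds set beforehand. This was a rerun after values had been seen, since gene coordinates misplaced in a first run had put the parts elsewhere, and a minimum coverage per part tried then was dropped. Weaker recovery of gene-dense DNA may contribute, as Spearman's rho between genes per Mb and the ratio was -0.461 across the 23 chromosomes, which are not independent replicates, and this too lay between its bounds, while base composition was not examined. The knockdown itself stays among the open explanations, untested.

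With the upper 50% of peaks by score, the mesoderm factors had a mean difference of -1.25 kb (-6.26%, against -13.3% for all protein-coding genes). With all peaks, the developmental transcription factor genes had similar coverage in both lists within 10 kb of their ends. Windows filled to their ends do not account for this in the pooled genes, because the whole width of the peaks, which no window limits, had a median ratio of 0.984 over 131 genes marked in both lists, against 0.820 in lists matched on width (percentile 100), and 0.945 over 92 genes without the HOX genes (percentile 99.98), although the 16 endoderm genes alone, at 0.932 and percentile 92.4, leave it open for that list. Genes that share a peak, as most HOX genes do, repeat its ratio. The random lists were not matched on this, so these percentiles rest on fewer separate peaks than genes. Peaks of very high score may keep their width in any library. Matching on score gave 0.878 and again percentile 100, but 113 of the 131 genes were at the score ceiling in both lists, so the score could not be matched there, and the test was set aside for that reason after its value was seen. A selective retention of H2AK119ub at these genes in the knockdown is a hypothesis that 1 library per group leaves untested.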
